A study of Mus musculus with 10 samples.

How the data were processed

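Gene expression was measured by RNA-seq in 10 whole mouse embryos at embryonic day 7.5, 5 wild type (WT) and 5 mutant for both Axin1 and Axin2. Total RNA (1.9 to 2 ng per embryo, RNA integrity numbers of 9.7 to 10) was turned into cDNA with the SMART-Seq v4 kit, which copies full-length polyadenylated RNA by template switching, and amplified for 12 cycles. Libraries were made from 10 ng of cDNA with the KAPA Hyper Prep kit. This chemistry does not record the strand of the RNA, so reads from overlapping genes on opposite strands cannot be told apart, and no molecular identifiers were used, so intervals and floors given for read counts cover counting error only. The mutants' labels read DKO, which commonly stands for double knockout; how the alleles were made and what transcript they leave, the strain of the animals and the litters are not given in the sources used here.

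Per the submitters' notes, reads were trimmed with cutadapt 1.6, aligned to the mouse build mm10 with STAR 2.5.0a, counted per gene with HTSeq 0.5.3 and scaled with DESeq (no version stated). The deposited values are a signal per gene and embryo: read counts that the authors divided by 1 size factor per embryo. This was checked on the values. For 20006 of 20006 listed genes, each embryo's values were whole multiples of 1 step within 0.01 reads (largest deviation 5.2e-10), and size factors recomputed from those whole numbers by the median-of-ratios method matched the steps to within 3.33e-14 percent. Size factors ran from 0.881 to 1.20. The listed genes had at least 15 reads summed over the embryos, and the filter that chose them is not stated. The 10 columns were matched to the embryos by the descriptions in the labels, and no column was left out. Reads recovered in this way totalled 20744547 to 28505209 per embryo, so that 3 reads, the floor used for a gene without reads, corresponded to 2.51 to 3.41 scaled counts per embryo.

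Genes with a mean scaled count of at least 10 over the 10 embryos were tested (15429 genes). The scaled counts were log2-transformed after adding 1, and the genotypes were compared with limma 3.58.1 (linear model with an intensity trend, the tool behind every adjusted p of a single gene) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Log2 fold changes are mutant over WT, given with their standard error (SE), and group values are means of scaled counts ± SD over 5 embryos. For single values, a two-sided exact permutation test over the 252 assignments of the embryos was used, which cannot give a p below 0.00794.

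Gene lists were tested by a list score, the mean log2 value of the tested members in each embryo, with the same exact permutation test and Benjamini-Hochberg adjustment over 34 lists. The lists covered WNT signalling (WNT/β-catenin target and feedback genes, WNT ligands, secreted WNT antagonists, the β-catenin destruction complex); cell types of the gastrula (epiblast and pluripotency, primitive streak, nascent mesoderm, paraxial and presomitic mesoderm, cardiac and lateral plate mesoderm, extra-embryonic mesoderm and allantois, blood and endothelium progenitors, definitive endoderm, node and axial mesoderm, ectoderm and neural plate, anterior visceral endoderm, visceral endoderm, parietal endoderm, extra-embryonic ectoderm and trophoblast, primordial germ cells); maternal decidua and blood cells; mesenchymal and epithelial genes; the BMP, NODAL, FGF, NOTCH and retinoic acid pathways; Hox genes of paralogue groups 1 to 4 and of 5 to 13; and cell cycle, p53 response, immediate early and heat shock, hypoxia and glycolysis, and Y-linked genes. Members past the threshold were counted over the genes tested and, with p-values adjusted over the list alone, within each list. Some genes sit in more than 1 list: 485 entries, 456 of them tested. Beside the exact test, camera was run with an inter-gene correlation estimated for each list, which compares a list with the other genes, and fry, which tests whether a list's genes move on balance 1 way. The lists, the tests, the alternatives except 1, and the rule for named genes were chosen before the data were examined.

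Named genes were Axin1 and Axin2; the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean scaled count of at least 50 and no overlap between the groups, leaving out predicted genes and pseudogenes named as such; and up to 4 members of each list with the smallest adjusted p, with single members that did not move like the rest. List members outside this rule were chosen after their values were seen and are given without an SE. The values of 2 genes that the rule names, and the summed copies of 1 of them, are not reported here. Coordinates and overlapping exons come from the GENCODE mouse annotation, release M21 (build GRCm38, the same assembly as mm10), matched by gene identifier for 15390 of the 15429 tested genes (99.75%), 14869 of them under the same symbol. Exons of Foxb1, Pcdh8, Rimbp2, Galnt16, Btrc, Ctnnb1, Apc2, Wnt5a, Wnt11, Sfrp2, Dll1, Fst, Bmp4, Gata6, Six3, Zeb1, Zeb2, Cubn, Grhl2, Hoxb2, Cdkn1a, Junb, Bnip3 and Ankrd37 overlap genes on the opposite strand, and those of Hoxc10, Hoxa9 and Hoxd11 overlap Hoxc5, Mir196b and Gm28309 on the same strand, so their values can hold reads of both; further overlaps stand beside the named genes. The annotation release used for counting is not given in the sources used here.

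The alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, scaling by totals, by upper quartile and by quantiles, weights per embryo, the embryo number as a block, the Y-linked level as a covariate, leaving out each embryo in turn, edgeR 4.0.16 (quasi-likelihood, TMM scaling) and DESeq2 1.42.0 on the recovered reads, camera, fry and the median of a list in place of its mean. A comparison of mutants 1, 2 and 5 with WT was added after the data were seen. The methods were tested on simulated data made from these libraries with known changes. At 5 embryos per group, limma called 17.9% of the genes changed 1.5-fold, 47.8% of those changed 2-fold and 68.2% of those changed 4-fold, with 5 false calls among 15214 unchanged genes. The share of 4-fold changes called was 66.7% with edgeR (4 false calls) and 77.3% with DESeq2 (30 false calls). In the simulation 15214 of 15429 genes were unchanged, whereas 25.13% were called in the data, so these shares need not hold for the real comparison. A simulated list with a true change of 1 was estimated at 1.12 (exact permutation p = 0.00794), and 1 of 33 unchanged lists had an exact p under 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for coordinates and plots.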

Results

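RNA-seq profiles were obtained from 10 whole mouse embryos at embryonic day 7.5, when gastrulation is under way and the first mesoderm has formed. WT embryos (n = 5) were compared with embryos mutant for Axin1 and Axin2 (n = 5), paralogous scaffold proteins of the complex that marks β-catenin for destruction and so restrains canonical WNT signalling. The comparison asks how mutation of both scaffold genes changes WNT signalling and the making of the different kinds of mesoderm. Each library held between 20744547 (WT 3) and 28505209 (WT 1) reads over 20006 listed genes, of which 18564 to 19184 had reads. The number of reads did not separate the genotypes (exact permutation p = 0.746). Mitochondrial genes took 0.190% to 0.686% of the reads.

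Mutant embryos had lost much of the expression of epiblast, nascent mesoderm, paraxial mesoderm, node and NODAL pathway genes, and expressed posterior Hox genes, allantois genes and several feedback targets of WNT at higher levels. The lists of these genes passed the exact permutation test (adjusted p = 0.0245 for each) but not camera with an estimated correlation between members (adjusted p = 0.171 to 0.587). The head and forebrain regulator Otx2 fell by 6.40 on the log2 scale (SE 1.11, n = 5 per group; −3.76 with DESeq2). The NODAL inhibitor Lefty2 fell by 7.30 (SE 0.57) and the pluripotency factor Pou5f1 fell by 3.99 (SE 0.48). Hoxc10, a posterior Hox gene, rose by 5.78 (SE 0.51) and the WNT feedback inhibitor Apcdd1 by 2.87 (SE 0.16). Of 15429 genes tested, 3877 (25.13%) changed, 1754 of them higher and 2123 lower in the mutants. At least 2-fold changes were found for 520 genes that rose and 1073 that fell, and at least 16-fold changes for 42 and 105. The groups did not overlap for 2639 genes (17.1% of those tested, against 0.794% by chance), 2471 of them among the genes that changed. The number of genes that changed was 2505 without WT 5 and 4535 without the library labelled mutant 4, and it was 3664 (1501 higher, 2163 lower) for mutants 1, 2 and 5 against WT.

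The genotypes separated on the first principal component, which held 47.7% of the variance. WT embryos lay between −73.3 and −51.8 on it and mutants 1, 2, 3 and 5 between 62.3 and 78.4. Between them, at 16.6, lay the library labelled mutant 4, which stood apart on component 2, at −91.3. Its correlation with the other mutants across genes was 0.933 to 0.944, against 0.958 to 0.974 among those mutants. It was 0.916 to 0.936 with WT embryos (genes are not independent replicates).

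**Figure D1:**
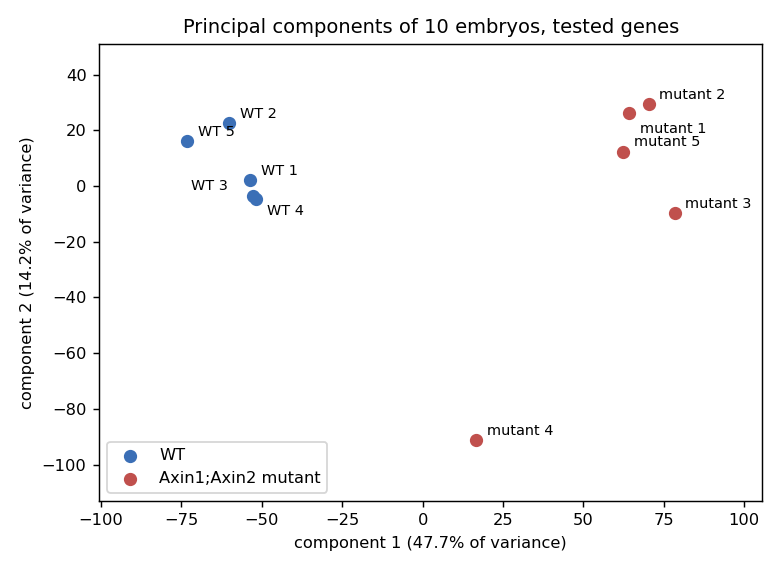
Scores of the 10 embryos on the first 2 principal components of the tested genes (log2 scaled counts, arbitrary units), with WT in blue and mutants in red. WT embryos lie between −73.3 and −51.8 on component 1, mutants 1, 2, 3 and 5 between 62.3 and 78.4, and the library labelled mutant 4 at 16.6.

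Axin1 transcripts were lower in each mutant than in any WT embryo, whereas Axin2 transcripts showed no difference past the threshold. Axin1 (ENSMUSG00000024182.16, chromosome 17, 26138688 to 26195811, plus strand, mm10) fell by 1.49 on the log2 scale (SE 0.21, adjusted p = 0.000614; exact permutation p = 0.00794), from 3551 ± 244.8 scaled counts in WT to 1343 ± 582.9 in mutants (SD, n = 5). Mutants 1, 2, 3 and 5 had 820 to 1319 counts, a mean of 30.8% of the WT mean, and the library labelled mutant 4 had 2336 (65.8%). Axin2 (ENSMUSG00000000142.15, chromosome 11, 108920349 to 108950783, plus strand), itself a transcriptional target of WNT signalling, measured 440.8 ± 43.12 in WT and 447.6 ± 113.6 in mutants, with a log2 fold change of −0.01 (SE 0.17, adjusted p = 0.981). Reads from both genes remained in the mutants, and since the structure of the alleles is not given, reads of a mutant transcript cannot be told from those of an intact one. Exons of Axin2 also overlap those of the antisense gene Gm11670.

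**Figure D2:**
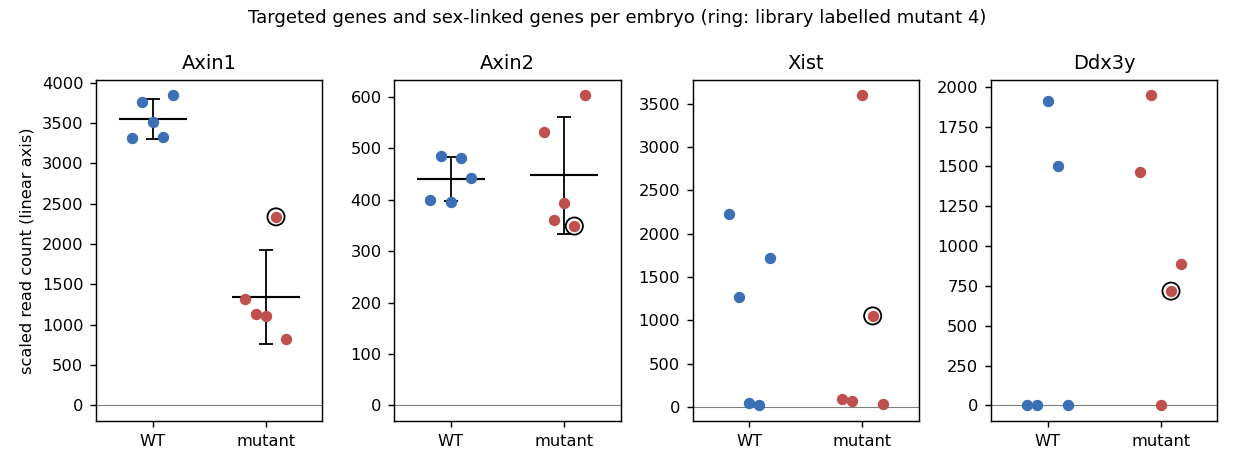
Scaled read counts per embryo of Axin1, Axin2, Xist and Ddx3y on linear axes, with group means and SD (n = 5) for Axin1 and Axin2 and a ring around the library labelled mutant 4. That library has 2336 counts of Axin1, between the mutants at 820 to 1319 and the WT embryos at 3314 to 3843, and reads of both Xist and Ddx3y.

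Among the 12 genes with the largest rise, 4 belong to the Hox clusters: Hoxc11 (chromosome 15, 102954427 to 102957708), Hoxc10 (102966796 to 102971893 on the same chromosome), Hoxa9 (chromosome 6, 52223100 to 52231089) and the antisense RNA Hoxaas3 (52175217 to 52215076). Hoxc11 rose by 5.92 (SE 0.51, adjusted p = 1.89e-05), from 1.27 ± 1.34 scaled counts to 127.5 ± 68.78 (SD, n = 5), and Hoxa9 by 5.18 (SE 0.47, adjusted p = 2.93e-05), from 17.44 ± 13.76 to 540.3 ± 137.1. Hoxaas3 rose by 5.76 (SE 0.33), although its exons overlap those of Hoxa3 and Hoxa7 on the opposite strand. The embryonic β-like globin Hbb-y rose by 5.37 (SE 0.64) and the homeobox gene Tlx2 by 5.05 (SE 0.65). The solute carrier Slco2b1 rose by 6.41 (SE 0.59, with exons that overlap 2 antisense genes). Tmem173, the adaptor STING of DNA sensing, rose from 5.867 ± 5.73 to 163.3 ± 55.83 scaled counts (SD, n = 5). The hair keratin gene Krt33a (chromosome 11, 100011195 to 100016212) had 0 reads in WT and 528 in mutants, at least 179-fold higher (floor of 3 counts over the WT group). The serine protease gene Prss56 had 1 and 584 reads, a ratio of 594 (95% counting interval 106 to 23500). Tpm3-rs7 (log2 fold change 4.75, SE 0.84) and Dynlt1b (4.98, SE 1.42) are near-identical copies of other genes. The summed reads of their families differed by 0.04 and 0.43. The call for Dynlt1b was lost without WT 1 (adjusted p = 0.0575), without WT 5 (0.0656), without mutant 2 (0.0506) and for mutants 1, 2 and 5 (0.0546), and with edgeR (0.198) and DESeq2 (0.294), where its log2 fold change was 2.08 and 2.09.

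The 12 genes with the largest fall included regulators of the head, of the streak's derivatives and of left-right and axial patterning. Otx2 (chromosome 14, 48657677 to 48673819) measured 734 ± 93.66 scaled counts in WT and 53.96 ± 111.2 in mutants (adjusted p = 0.00177; SD, n = 5), with 252.7 in the library labelled mutant 4. Its log2 fold change ran from −7.62 without that library to −3.76 with DESeq2, and those of Foxc2 and Pcdh8 from −6.95 to −3.48 and from −7.61 to −4.32 in the same alternatives. Exons of Otx2 overlap the antisense RNA Otx2os1. Lefty2 (chromosome 1, 180893108 to 180899103) went from 1719 ± 1480 to 9.313 ± 7.558 (adjusted p = 1.21e-05). Cer1, a secreted antagonist of NODAL and BMP (chromosome 4, 82881751 to 82885148), went from 1889 ± 371.3 to 61.88 ± 75.67 (log2 fold change −6.04, SE 0.80). The forkhead gene Foxc2 of paraxial mesoderm (−5.82, SE 1.03) and the protocadherin Pcdh8 of presomitic mesoderm (−6.50, adjusted p = 0.00158) fell. So did the junctophilin Jph4 (−6.55, SE 0.79) and the active-zone gene Rimbp2 (−6.02, SE 0.63). The forkhead gene Foxb1 (−7.84, SE 1.22), the guanine exchange factor Mcf2 (−6.51, SE 1.07) and the glycosyltransferase Galnt16 (−5.98, SE 1.06) fell with limma. DESeq2 gave smaller falls (−4.36, −3.87 and −3.36) and did not call these genes (adjusted p = 0.116, 0.132 and 0.089), and edgeR did not call Galnt16 (−3.37, adjusted p = 0.0538). Ifi204, an interferon-inducible gene of a family with many copies on chromosome 1, fell by 7.83 (SE 0.76).

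Among WNT genes, the feedback inhibitors Apcdd1, Nkd1, Nkd2 and Notum and the caudal homeobox genes Cdx1 and Cdx4 rose while T and the ligands Wnt3 and Wnt3a fell. The WNT/β-catenin target and feedback list rose by 0.98 in score, above every WT embryo in 5 of 5 mutants (exact permutation p = 0.00794, adjusted p = 0.0245). It had an adjusted p = 0.493 with an estimated correlation. Of 19 tested members, 11 rose and 3 fell (14 and 4 adjusted over the list alone). The feedback inhibitors Apcdd1, Nkd2 (from 134.3 ± 34.13 to 1094 ± 332.3 scaled counts), Nkd1 (2.44, SE 0.26) and Notum (3.34) rose. So did the caudal homeobox genes Cdx4 (4.13, SE 0.40) and Cdx1 (2.60) and the receptor Lgr5 (1.07). Dkk1 (0.59, adjusted p = 0.0509), Znrf3 (0.38, adjusted p = 0.0998) and the caudal gene Cdx2 (0.56, adjusted p = 0.122) did not pass the threshold. Neither did Ccnd1 (0.06, adjusted p = 0.785) nor Sp5 (−0.53, adjusted p = 0.077), which was lower adjusted over the list alone. The members that fell were the mesoderm factors T (−1.62, SE 0.19) and Msgn1 (−1.93) and the zinc finger gene Sp8 (−2.57). T, or Brachyury, went from 2392 ± 508.7 to 787.2 ± 215.8 scaled counts (SD, n = 5).

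WNT ligands went both ways. Of 15 tested, Wnt4 (2.02, SE 0.28), Wnt11 (1.42, SE 0.21), Wnt5a (1.25, SE 0.18) and Wnt5b (1.22) rose. Wnt8a (−4.17), Wnt2b (−3.27, SE 0.56), Wnt3a (−2.51), Wnt2 (−1.19) and Wnt3 (−1.08), which is needed to form the streak, fell (the same 4 and 5 adjusted over the list alone). The list score differed by −0.40 (adjusted p = 0.184), with a median member at 0.06 and camera pointing upwards. Without the library labelled mutant 4 it differed by −0.59 (adjusted p = 0.03). Of 9 secreted WNT antagonists, Dkk3 (2.21, SE 0.21) and Wif1 (2.08) rose. Cer1, Sfrp1 (−3.77, SE 0.74), Sfrp2 (−1.55, SE 0.25) and Frzb (−1.37) fell (3 higher and 4 lower adjusted over the list alone). The score differed by −0.77 (adjusted p = 0.0809) against a median member at 0.37. It passed in 5 of 22 alternatives, among them without the library labelled mutant 4 (−0.98, adjusted p = 0.0208) and with the median of its members in each embryo (−1.74, adjusted p = 0.0225). The member with the largest change was Cer1 (−6.04), and a score without it was not computed. The destruction complex list, which leaves out the Axin genes, fell by 0.40 in score, below every WT embryo in 4 of 5 mutants (exact permutation p = 0.0159, adjusted p = 0.0386). It had an adjusted p = 0.68 with an estimated correlation. Of its 9 members, the ubiquitin ligase subunit Btrc (−0.79, SE 0.10) and β-catenin itself, Ctnnb1 (−0.24, SE 0.08, adjusted p = 0.0375), fell, and 3 did so adjusted over the list alone. Most of the fall in score came from Apc2 (−2.72, adjusted p = 0.052): without it, a test chosen after the values were seen, the score differed by −0.11 (exact permutation p = 0.0873), and with the median of the members by −0.19 (adjusted p = 0.188). The call for this list was lost in 11 of 22 alternatives, among them each comparison without 1 WT embryo except WT 1 and each without 1 mutant except the library labelled mutant 4 (score differences of −0.403 to −0.35). The call for Ctnnb1 was lost in 10 of 23, among them without WT 3, 4 or 5 or any 1 mutant (log2 fold changes of −0.26 to −0.21).

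Pluripotency and early mesoderm genes fell together. The epiblast and pluripotency list fell by 2.25 in score, below every WT embryo in 5 of 5 mutants (exact permutation p = 0.00794, adjusted p = 0.0245), but had an adjusted p = 0.171 with an estimated correlation. Of 17 tested members 12 fell and 0 rose (12 and 1 adjusted over the list alone). Pou5f1 (exons overlap the antisense gene Gm19553) went from 6875 ± 797.4 to 573.9 ± 466.1 scaled counts (SD, n = 5). The DNA methyltransferase Dnmt3b (−1.46, SE 0.12), the kinase Pim2 (−3.08, SE 0.27), the amino acid transporter Slc7a3 (−3.92, SE 0.43) and Nanog (−2.84) fell. Nascent mesoderm genes fell by 2.47 in score in 5 of 5 mutants (adjusted p = 0.0245; adjusted p = 0.241 with an estimated correlation). In this list 11 of 15 members fell and 2 rose, the same counts as adjusted over the list alone. Of those that fell, Dll1, Dll3, Tbx6, Msgn1 and Ripply2 are also in the paraxial list. Mesp1, a factor of the first cardiac and cranial mesoderm, fell by 4.27 (SE 0.45), and the apelin receptor Aplnr fell by 1.56 (SE 0.16). The members that rose were the streak homeobox gene Evx1 (1.27) and the ligand Fgf10 (1.09).

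The paraxial and presomitic mesoderm list fell by 3.19 in score, below every WT embryo in 5 of 5 mutants (exact permutation p = 0.00794, adjusted p = 0.0245; adjusted p = 0.493 with an estimated correlation). Of 16 members, 12 fell (13 adjusted over the list alone) and 0 rose. The T-box factor Tbx6 (−4.17, SE 0.65), the NOTCH ligands Dll3 (−5.55, SE 0.62) and Dll1 (−3.64, SE 0.42) and the segmentation clock gene Hes7 (−4.57) fell. In the library labelled mutant 4 the score lay only 0.64 below the WT mean, and without that library the difference was −3.83. NOTCH pathway genes had a score difference of −1.33 (adjusted p = 0.071) that was −1.70 without the library labelled mutant 4 (adjusted p = 0.0208). It passed in 6 of 22 alternatives. Of 14 members 7 fell, among them Notch1 (−2.10, SE 0.35, overlapping antisense genes), and 2 rose, among them the effector Hey2 (2.09, SE 0.28). The counts were 8 and 2 adjusted over the list alone. Dll1, Dll3, Hes7 and Lfng, which fell, are in both the NOTCH and the paraxial list. The primitive streak list itself did not pass the test, with a score difference of −0.43 (adjusted p = 0.071). Of its 15 members 6 fell and 5 rose (8 and 5 adjusted over the list alone). Its homeobox genes diverged: Mixl1 rose by 2.32 (SE 0.49) while Lhx1 fell by 2.14 (SE 0.28), and the activin antagonist Fst fell by 1.64 (SE 0.38). The list passed the test in 3 of 22 alternatives, among them without mutant 1 (−0.54, adjusted p = 0.0385).

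**Figure D3:**
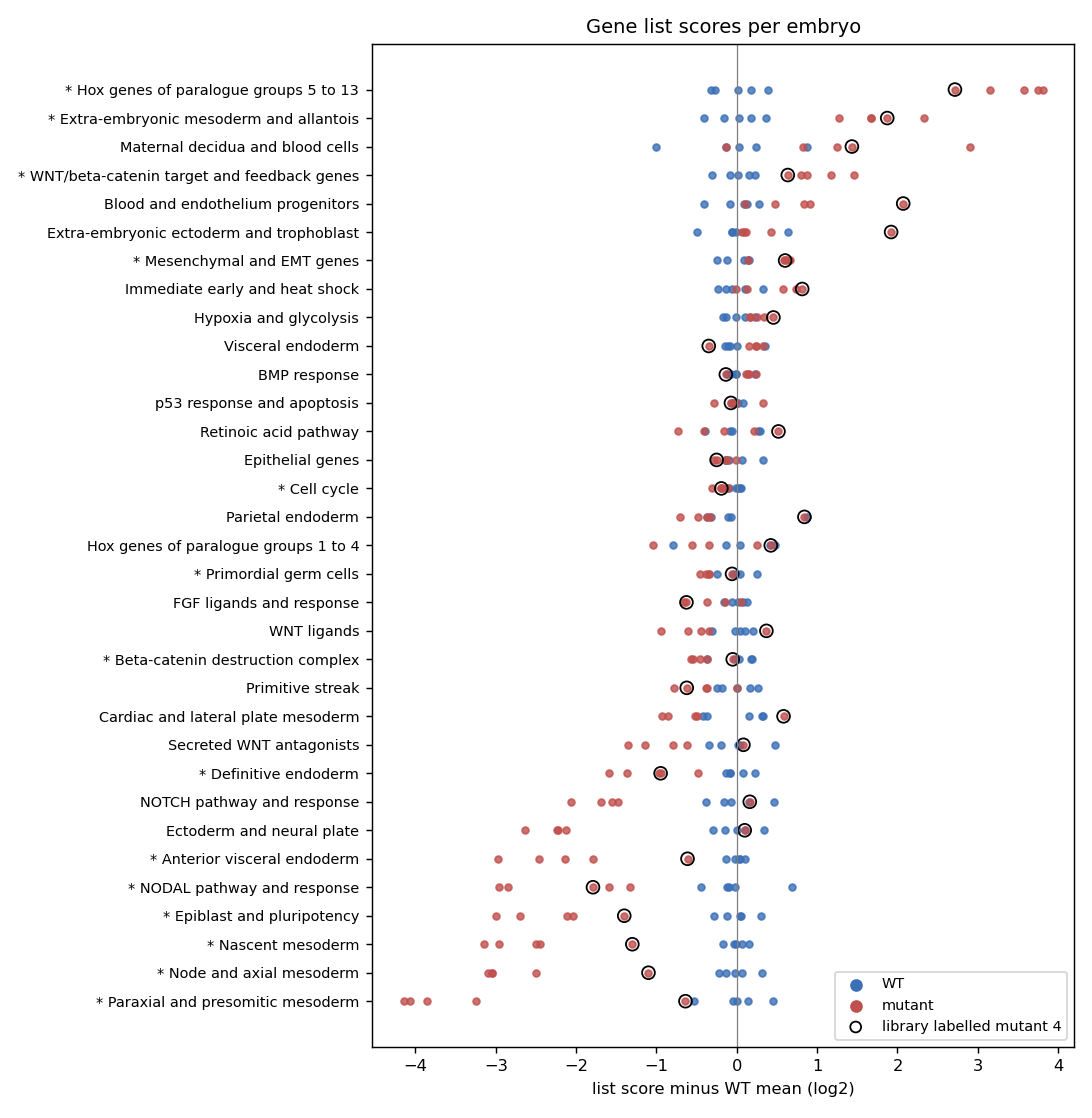
Score of each gene list except the Y-linked genes in each embryo, minus the WT mean (log2 units), with WT in blue, mutants in red, a ring around the library labelled mutant 4 and an asterisk at each list past the threshold. The paraxial and presomitic mesoderm list fell by 3.19 and the list of Hox genes of paralogue groups 5 to 13 rose by 3.40, and the ringed library lies at −0.64 and 2.71.

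Axial and anterior genes and some definitive endoderm genes were lower as well. Scores of the node and axial mesoderm list (−2.56), the definitive endoderm list (−1.07) and the anterior visceral endoderm list (difference of −1.995) each fell below every WT embryo in 5 of 5 mutants (exact permutation p = 0.00794, adjusted p = 0.0245 for each). In this order they had an adjusted p = 0.22, an adjusted p = 0.652 and an adjusted p = 0.531 with an estimated correlation. Of 13 node genes 10 fell, as many as adjusted over the list alone, and 0 rose. They included the homeobox gene Noto (−5.58), the cilia regulator Foxj1 (−4.49, SE 0.37), the flow sensor Pkd1l1 (−5.07, SE 0.56), Shh (−1.92) and the BMP antagonist Chrd (−2.44, SE 0.29, exons overlapping Thpo). Of 9 definitive endoderm genes only Cer1, Trh (−3.45, SE 0.47) and Foxa1 (−1.70, SE 0.32) fell (3 lower and 1 higher adjusted over the list alone). Foxa2 measured −0.31 and Sox17 0.28, neither past the threshold. Of 9 anterior visceral endoderm genes, Cer1, Otx2, Lhx1 and Sfrp1 fell (5 lower and 1 higher adjusted over the list alone), and each of these sits in another list as well. The other members, Hhex (0.28), Dkk1 (0.59), Sfrp5 (0.59), Gsc (0.57) and Hesx1 (−1.63), were not past the threshold. NODAL pathway genes fell by 2.10 in score in 5 of 5 mutants (adjusted p = 0.0245; adjusted p = 0.587 with an estimated correlation). Of 10 members 5 fell, among them the co-receptor Tdgf1 (−5.23) and the cofactor Foxh1 (−1.56, SE 0.21), and 2 rose, among them Mixl1. The counts were 6 and 2 adjusted over the list alone.

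Ectoderm and neural plate genes had a score difference of −1.83 that did not pass the test (adjusted p = 0.0634). It was −2.31 without the library labelled mutant 4 (adjusted p = 0.0208), in which the score lay 0.10 above the WT mean. It passed in 6 of 22 alternatives, such as the median of the members (−2.88, adjusted p = 0.0225). Of 13 members 7 fell (8 adjusted over the list alone), among them the forebrain gene Six3 (−5.18, SE 1.08; not called by edgeR, at −2.96 with adjusted p = 0.0653, or DESeq2, at −2.95 with adjusted p = 0.102) and Zic2 (−1.87, SE 0.31). Zic1 rose, with 2 reads in WT and 114 in mutants, a ratio of 58 (95% counting interval 15.7 to 485), and its exons overlap Zic4 on the opposite strand.

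Posterior Hox genes rose in all 4 clusters. Of 23 tested genes of paralogue groups 5 to 13, 22 rose, as many as adjusted over the list alone, and 0 fell. The score rose by 3.40, above every WT embryo in 5 of 5 mutants (exact permutation p = 0.00794, adjusted p = 0.0245; adjusted p = 0.171 with an estimated correlation). The rises ran from 0.79 (Hoxb5) to 5.92 (Hoxc11), and Hoxc13 measured 0.97 (SE 0.58, adjusted p = 0.244). Hoxa11 rose from 32.5 ± 6.397 to 672 ± 312.7 scaled counts (SD, n = 5; exons overlap the antisense RNA Hoxa11os) and Hoxd11 from 12.66 ± 5.911 to 341.6 ± 117.8. Anterior Hox genes, of groups 1 to 4, had no common direction: the score differed by −0.25 (adjusted p = 0.531; camera pointed upwards), from −0.45 without WT 1 to −0.06 without mutant 2 and −0.42 without the library labelled mutant 4. Hoxb1, a hindbrain and early streak Hox gene, fell by 2.79 (SE 0.48), and Hoxc4 rose by 2.42 (SE 0.31). Of 9 tested, 2 rose and 1 fell (2 and 3 adjusted over the list alone). The other call was for Hoxd1 (0.73, SE 0.23, adjusted p = 0.0379), which was lost without WT 1, 3, 4 or 5 and without mutant 1, 2, 3 or 5 (0.57 to 0.77).

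**Figure D4:**
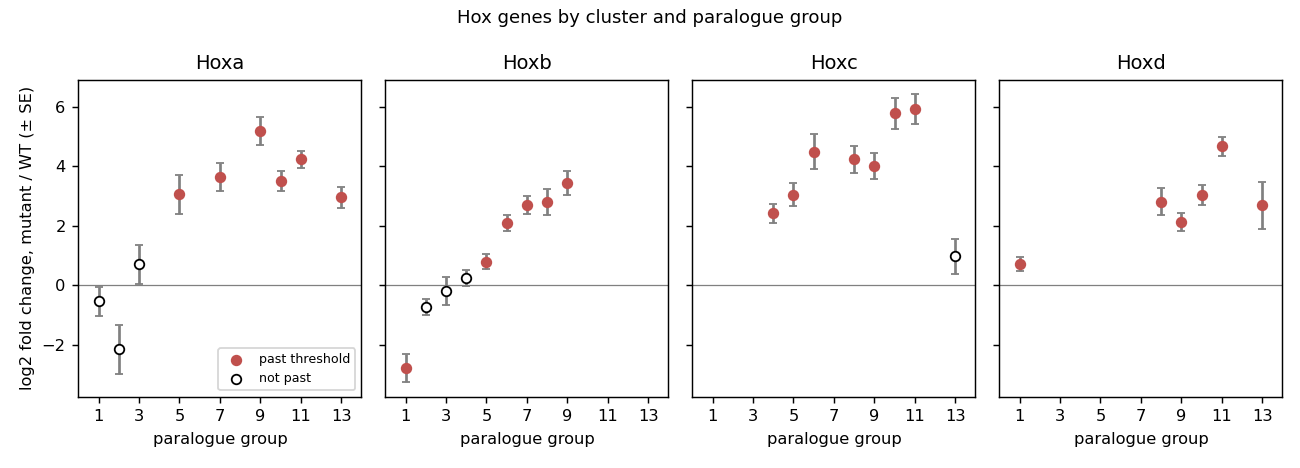
Log2 fold change, mutant over WT, of each tested Hox gene with its SE (n = 5 per group), by cluster and paralogue group, with filled points for genes past the threshold. Of the genes of groups 5 to 13, 22 of 23 rose, and of those of groups 1 to 4, 2 rose and Hoxb1 fell.

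Genes of the allantois and of mesenchyme were higher. The extra-embryonic mesoderm and allantois list rose by 1.77 in score in 5 of 5 mutants (exact permutation p = 0.00794, adjusted p = 0.0245; adjusted p = 0.171 with an estimated correlation). Of 17 members 10 rose (11 adjusted over the list alone) and 0 fell. Of the genes that rose, 4 (Hoxa10, Hoxa11, Hoxa13 and Hoxc10) are also in the list of posterior Hox genes, and the others included Tbx4 (3.67), a T-box gene of the allantois and hindlimb, Pitx1 (2.14) and the ligand Bmp4 (1.03, SE 0.19). Extra-embryonic mesoderm genes Hand1 (−0.09), Foxf1 (0.39), Ahnak (−0.09) and Vcam1 (−2.10) were not past the threshold. Mesenchymal and EMT genes rose by 0.52 in score, above every WT embryo in 4 of 5 mutants (exact permutation p = 0.0159, adjusted p = 0.0386; adjusted p = 0.587 with an estimated correlation). Of 12 members 5 rose and 1 fell, also adjusted over the list alone. The cadherin Cdh11 rose by 2.10 (SE 0.16) and the repressor Zeb1 by 2.66 (SE 0.26), while its relative Zeb2 fell by 0.73 (SE 0.18). This call was lost in 8 of 22 alternatives, among them without WT 1, 2, 3 or 5 (0.46 to 0.56). Epithelial genes had a score difference of −0.16 (adjusted p = 0.184), with 4 of 13 lower, also adjusted over the list alone, among them E-cadherin, Cdh1 (−0.78, SE 0.08), and Epcam (−0.57, SE 0.09).

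Cardiac and blood lists did not pass the test. Cardiac and lateral plate genes had a score difference of −0.44 (adjusted p = 0.259), which was −0.70 without the library labelled mutant 4 (adjusted p = 0.0426). Of 18 members 3 rose and 3 fell (3 and 4 adjusted over the list alone). They were Bmp4, Gata6 (0.59, SE 0.12) and Actc1 (1.59, SE 0.35) against Gata5 (−2.22), Smarcd3 (−1.79) and the myosin light chain Myl7 (−3.02, SE 0.50). Blood and endothelium genes had a score difference of 0.88 (adjusted p = 0.0506). Of 18 members 6 rose, also adjusted over the list alone, among them Lmo2 (1.90, SE 0.19), Fli1 (0.79, SE 0.13) and Itga2b (1.56, SE 0.30). The score of the library labelled mutant 4 lay 2.07 above the WT mean, and the difference was 0.58 without it, while the list passed the test in 6 of 22 alternatives, among them without mutant 2 (1.07, adjusted p = 0.0225). Primordial germ cell genes fell by 0.32 in score, below every WT embryo in 4 of 5 mutants (exact permutation p = 0.0159, adjusted p = 0.0386; adjusted p = 0.762 with an estimated correlation). Of 8 members Dppa3 (−2.22, SE 0.61) and Dnd1 (−1.65, SE 0.37, exons overlapping Wdr55) fell and Prdm1 (1.79, SE 0.20), which is also made in endoderm, rose, with the same counts adjusted over the list alone. This call was lost in 16 of 22 alternatives, among them without WT 1, 3, 4 or 5 and without mutant 1, 2, 3 or 5 (−0.332 to −0.258).

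Lists of extra-embryonic endoderm, of trophoblast and of maternal cells did not pass the test. Visceral endoderm genes had a score difference of 0.12 (adjusted p = 0.512; 0.24 without the library labelled mutant 4 and 0.07 without mutant 2), with 3 of 18 higher and 1 lower, also adjusted over the list alone. Apom measured 0.85 (SE 0.23), Cubn 0.60 (SE 0.17), Hnf4a 0.56 (SE 0.17) and Cthrc1 −1.33 (SE 0.28). Parietal endoderm genes had −0.21 (adjusted p = 0.531), which was −0.47 without the library labelled mutant 4 and 0.01 without WT 1, with 1 of 10 lower (Plat, −1.38, SE 0.43) and 0 adjusted over the list alone. Extra-embryonic ectoderm and trophoblast genes had 0.52 (adjusted p = 0.259) and 0 of 17 members past the threshold with limma, also adjusted over the list alone. The library labelled mutant 4 lay 1.92 above the WT mean, and without it the difference was 0.17. Maternal decidua and blood cell genes had 1.25 (adjusted p = 0.106; 1.98 and adjusted p = 0.045 with the median of the members), with 3 of 12 higher, also adjusted over the list alone. These were the decidual prolactin Prl8a2 (4.03, SE 0.89), the granulocyte gene S100a8 (2.55, SE 0.82) and the adult globin Hba-a2 (5.59, SE 1.36), whose summed reads with its copy Hba-a1 differed by −0.775 (exact permutation p = 0.198). In mutant 3 the maternal score was 8.859, against 5.826 to 7.394 in the other mutants and 4.955 to 6.835 in WT embryos. That embryo also had the highest scaled counts of Prl8a2 (7017) and S100a8 (137.8). The calls of single members ended without WT 1 or 5 or mutant 1, 2, 3 or 5 for Cubn (0.53 to 0.58). They ended without WT 1, 4 or 5 or mutant 1, 2, 3 or 5 for Hnf4a (0.48 to 0.56) and Plat (−1.37 to −1.19), and without WT 1, 2 or 5 or mutant 2, 3 or 5 for S100a8 (1.85 to 2.71).

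Of the remaining signalling and cell state lists, only the cell cycle list passed the test. It fell by 0.19 in score, below every WT embryo in 5 of 5 mutants (exact permutation p = 0.00794, adjusted p = 0.0245, and adjusted p = 0.531 with an estimated correlation). With the median of its members the call was lost (−0.184, adjusted p = 0.0852). Of 17 members 7 fell (9 adjusted over the list alone) and 0 rose. The replication licensing genes Mcm3 (−0.70, SE 0.10), Mcm2 (−0.64, SE 0.10) and Mcm5 (−0.48, SE 0.08) and the cyclin Ccne1 (−0.50, SE 0.09) fell. BMP response genes had a score difference of 0.10 (adjusted p = 0.308), from 0.065 without mutant 1 to 0.158 without the library labelled mutant 4. It was 0.81 with the median of the members, and past the threshold (adjusted p = 0.0337). Of 12 members 4 rose and 1 fell (5 and 1 adjusted over the list alone). Bambi measured 1.13 (SE 0.17) and Id4 −2.04 (SE 0.35, overlapping antisense genes). FGF genes had −0.35 (adjusted p = 0.0859) with a median member at 0.09 and camera pointing upwards. Of 16 members 4 rose, among them Fgf17 (1.58) and Fgf8 (0.89), and 4 fell, among them Fgf5 (−4.17, SE 1.03) and Etv1 (−2.13, SE 0.24), the same counts adjusted over the list alone. Without mutant 1 the FGF list passed, at −0.45 (adjusted p = 0.0385). Retinoic acid genes had −0.11 (adjusted p = 0.646) with a median member at 0.34 and camera pointing upwards. The difference ran from −0.27 without the library labelled mutant 4 to 0.04 without mutant 1. Of 11 members 3 rose, also adjusted over the list alone, among them Rdh10, which makes retinal (1.13, SE 0.14). The p53 response list had −0.02 (adjusted p = 0.786; camera pointed upwards), from −0.11 without mutant 3 to 0.05 without mutant 1. Of its 13 members the cell cycle inhibitor Cdkn1a rose (1.25, SE 0.28) and the apoptosis genes Pmaip1 (−1.56, SE 0.37) and Bbc3 (−0.72, SE 0.22) fell, also adjusted over the list alone. The call for Bbc3 was lost without WT 2 or 5 or mutant 1 or 2 (−0.66 to −0.61). Immediate early and heat shock genes had 0.45 (adjusted p = 0.0859), with 3 of 11 higher, also adjusted over the list alone, among them Egr1 (2.12, SE 0.29) and Atf3 (1.42, SE 0.20). Hypoxia and glycolysis genes had 0.28 (adjusted p = 0.0506), and passed in 4 of 22 alternatives, among them without WT 1 (0.33, adjusted p = 0.0415) and with the median of the members (0.585, adjusted p = 0.045). Of 14 members 3 rose (4 higher and 2 lower adjusted over the list alone), among them Ankrd37 (0.83, SE 0.20).

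Sex-linked transcripts divided the embryos across the genotypes. Of the 10 embryos, 4 (WT 1, 2 and 5 and mutant 3) had at most 1.01 scaled counts of the Y-linked gene Ddx3y and 1268 to 3597 of Xist, the RNA that silences an X chromosome in female cells. Another 5 had 890 to 1947 of Ddx3y and at most 87.8 of Xist. Both were present in the library labelled mutant 4, with 717.6 counts of Ddx3y and 1050 of Xist. The Y-linked list had a score difference of 3.33 (exact permutation p = 0.524, adjusted p = 0.557), with 0 of 4 members past the threshold with limma, also adjusted over the list alone.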

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

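The tests of maternal tissue, of a milder response of 1 embryo and of a swap for the library labelled mutant 4, the values of Ifi204, Dynlt1b, Hba-x and prolactins beside them, and the test of changes of at least 16-fold near the targeted genes, were chosen only after the result was seen. The other tests in this part were written before their own results were seen. Those of a mixture and of near-identical copies concern a library and genes that these data had already shown. Each value below is the gap from the highest or lowest embryo of a genotype to the nearest other embryo, divided by the range of the 5 embryos, where it exceeded the 95% limit for 5 values. Of 356 groups of values tested, 44 did so, against 17.8 for chance, which flags about 1 in 20 groups. The library labelled mutant 4 was the embryo apart in 20 of the 32 found among mutants.

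The library labelled mutant 4 lay between the genotypes. Its epiblast and NODAL scores were 1.40 and 1.79 below the WT mean and its neural and NOTCH scores 0.10 and 0.16 above it. Its paraxial score, 7.628, was just under the lowest WT score of 7.739, although single paraxial genes lay far below each WT embryo, such as Dll3 (358.8 scaled counts, against at least 1823) and Foxc2 (372.9, against at least 712.2). Its Axin1 count was 0.705 of the lowest WT value and no WT library lay at the level of the mutants, which argues against a swap between these libraries but not against one with a sample outside the set. Xist was 12 times the highest value of the embryos with Y-linked reads, and the genes that fell in the other mutants lay at a median of 0.315 of the way back to WT (quartiles 0.116 to 0.574), which argues against a single milder embryo of 1 sex with ordinary sex-linked expression and against maternal tissue as the whole cause. A mixture with RNA of a WT-like embryo may account for part of it: the shares were 0.315 for genes that fell, 0.5 for genes that rose (quartiles 0.13 to 0.731) and 0.505 for Axin1. The medians differed by 0.185, just inside the limit of 0.2 set before the shares were known, though mutant 2 also gave 0.311 for genes that rose. A mixture with an embryo like these WT embryos would lift each gene that fell by a like share, but some were not lifted. Dnmt3b had 9789 scaled counts, against 10800 to 14550 in the other mutants and at least 26690 in WT. T had 615.5, against 582.1 to 1031 in the other mutants and at least 1821 in WT. Nor does a mixture account for the whole library: Prl4a1 (23750 scaled counts), Prl2a1 (5899), Prl7d1 (2977) and Hba-x (1185) were far above the highest WT values (234, 94.46, 0.9388 and 3.407). The trophoblast score lay 1.92 above the WT mean, so that extra trophoblast or yolk sac tissue, which was not tested, stays open for these genes. Ifi204 (share −0.00987) stayed at the level of the other mutants and Dynlt1b (222.3 scaled counts, against 365.2 to 383.9 in the other mutants) did not, so a second source, if there was one, shared the mutants' level of Ifi204; a mutant with unusual sex chromosomes and a partial phenotype was not tested.

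Several of the largest changes were in near-identical copies of other genes, where single genes differed far more than their families. Summed over the copies, 2 of 3 families differed by less than 0.5 on the log2 scale: Tpm3 with Tpm3-rs7 by 0.04 and the Dynlt1 copies by 0.43, against 4.75 and 4.98 for the single genes, while the Hba-a pair differed by −0.775 against 5.59 for Hba-a2 alone. Reads shared between near-identical copies may therefore make up most of the single changes, although the Dynlt1 sum still differed between the genotypes (exact permutation p = 0.00794). A family sum cannot tell read sharing from a variant that moves reads from 1 copy to another. Single copies also varied within a genotype. Dynlt1b had 212.4 and 193 scaled counts in WT 2 and 4 and at most 0.9388 in other WT embryos. Tpm3-rs7 had 219.2 in mutant 2 and 12680 in mutant 3. Genes within 10 Mb of Axin1 or Axin2 changed about as often as genes elsewhere (176 of 645, odds ratio 1.12, 95% interval 0.933 to 1.34, Fisher's exact p = 0.211). Of the 3 single genes 0 lie there, so by position alone linked variants within that distance are not at these genes. The odds ratio, taken over other genes, cannot decide their source. Variants at the other copies of each family were not tested. For changes of at least 16-fold the odds ratio was 1.5 (9 genes, 95% interval 0.667 to 2.94, Fisher's exact p = 0.215), so linked variants stay open for single strong changes such as that of Krt33a, at 8.9 Mb from Axin2. Dynlt1b, at 19.7 Mb from Axin1, lies outside the 10 Mb, so a longer stretch of another strain's chromosome stays open for that gene.

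The library labelled mutant 4 was highest among mutants for Foxb1 (gap of 1 of the range), Mcf2 (1), Galnt16 (0.773), Dll3 (0.836), Dll1 (0.835), Plat (0.742) and Id4 (0.868). The same library was lowest for Dynlt1b (0.908), Apom (0.841), Cubn (0.85), Prdm14 (0.835) and Cyp26a1 (0.755). Among list scores it was highest for paraxial and presomitic mesoderm (0.743), cardiac and lateral plate mesoderm (0.711), ectoderm and neural plate (0.814), parietal endoderm (0.76), extra-embryonic ectoderm and trophoblast (0.807), primordial germ cells (0.723) and NOTCH pathway genes (0.738), and lowest for visceral endoderm (0.743).

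Mutant 1 was lowest for Hba-a2 (0.779). Mutant 2 was lowest for Tpm3-rs7 (0.803; 219.2 scaled counts, near the WT mean of 135.8), Twist1 (0.733), Hoxc4 (0.747) and the mesenchymal and EMT score (0.872). Mutant 3, the only mutant without Y-linked reads, was lowest for Eif2s3y (0.875), Ddx3y (0.868), Uty (0.894), Kdm5d (0.879) and their list score (0.885), and for Aplnr (0.819) and Hoxb2 (0.801).

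Among WT embryos, WT 1 was highest for Prss56 (1, from a single read), Lama1 (0.736), Lamb1 (0.749) and the parietal endoderm score (0.758), and lowest for Apc2 (0.77). WT 2 was highest for Hnf4a (0.785) and lowest for Amer1 (0.758). WT 3 was highest for Slco2b1 (1) and lowest for Actc1 (0.772). WT 4 was lowest for Pcdh8 (0.84), and WT 5 was highest for Chrd (0.716) and Zic1 (1).

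Chance is an unlikely source of the number of genes that changed. Of 100 splits of the 10 embryos into 5 and 5, drawn from 126, 1 gave as many as the 3877 of the genotypes, the genotype split itself. The highest other split, which exchanged WT 2 and the library labelled mutant 4, gave 396, and the median of the other splits was 0. Such splits cannot tell genotype from another difference between the groups, such as litter or strain, which are not given.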

How the results depend on the processing

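The comparison of mutants 1, 2 and 5 with WT was chosen only after the result was seen. The number of genes that changed ranged from 2505 (without WT 5) to 4535 (without the library labelled mutant 4) when 1 embryo was left out, and the genes higher in mutants from 1071 to 2061 in the same comparisons. The other alternatives gave 3253 (embryo number as a block) to 4873 (weights per embryo, with 0.438 for the library labelled mutant 4). No gene called with all embryos changed sign in any alternative in which it was tested. Scaling by totals or by upper quartile left the number of calls at 3880 and 3889 but lowered the share of rises to 35.7% and 36.1%, against 45.2%, and moved the median log2 fold change from 0.01 to −0.04. With fewer embryos fewer genes were called, except without WT 3 (4058) or the library labelled mutant 4. DESeq2 called 4533 genes and edgeR 3596. With the embryo number as a block, although the numbers did not pair the embryos (correlations of −0.079 to 0.079), 3253 genes changed (1436 higher, 1817 lower) and 19 lists. With the Y-linked level as a covariate 3394 genes changed.

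Among the named genes, 3112 of the values under alternatives kept their side of the threshold, 110 lost a call, 58 gained one and 0 of the called ones reversed. Values without a call could change sign. Axin1 stayed lower in 23 of 23 alternatives (−1.73 to −1.34, largest adjusted p = 0.00285), and Axin2 stayed within −0.12 to 0.15. Calls that 6 or more alternatives ended were those of S100a8, Pdk1, Ctnnb1, Hoxd1, Bbc3, Junb, Cubn, Plat, Grhl2, Crabp1, Bnip3, Dynlt1b and Hnf4a.

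Camera with an estimated correlation called 0 of 34 lists, against 14 in the exact permutation test. It asks whether a list differs from the other genes and allows for members that vary together, and fry called the same 14 except the primordial germ cell list, with blood (adjusted p = 0.0127), ectoderm (0.0122) and NOTCH genes (0.0143) added. Camera apart, 10 of the 14 lists kept their call in each alternative run, leaving out each embryo in turn included. With the median of the members in place of the mean 18 lists were called, with the epiblast list at −0.758, and those of secreted WNT antagonists, ectoderm, maternal cells, BMP, NOTCH and hypoxia genes were added. The cell cycle list lost its call with the median of its members (adjusted p = 0.0852). The destruction complex, mesenchymal and primordial germ cell lists lost theirs in 11, 8 and 16 of 22 alternatives. The cause of these losses was not tested. Of the list values, 665 kept their side, 47 lost a call, 36 gained one and 0 of the called ones reversed. Depth limited low values: a gene without reads could hold up to 3 reads per library, 2.51 to 3.41 scaled counts.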

Other observations

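The 8 gene families of this part, and the tests of extra-embryonic mesoderm and of developmental stage, were chosen only after the result was seen; the test of read depth was written before. Camera and fry were not run on these families. Genes of motile cilia, which drive flow at the node, fell by 2.29 in mean score, below every WT embryo in 5 of 5 mutants (exact permutation p = 0.00794, adjusted p = 0.0212 over the 8 families). Of 19 cilia genes tested, 14 fell and 0 rose, among them the tektins Tekt4 (−4.78) and Tekt2 (−3.19) and the radial spoke gene Rsph4a (−4.47). Foxj1 and Tppp3, which fell, are also in the node list. Long non-coding RNAs of the Hox clusters rose by 1.88 in 5 of 5 mutants (adjusted p = 0.0212), with 5 of 8 higher, such as Hoxb5os (3.42) and Hoxd3os1 (2.43), though without strand information reads of the neighbouring Hox genes can be among them. Frizzled and LRP receptors, which bind WNT ligands, fell by 0.57 in 5 of 5 mutants (adjusted p = 0.0212): of 12, Fzd2 (−2.28), Fzd8 (−2.15), Fzd7 (−1.40) and Fzd6 (−0.58) fell and Fzd10 (1.36) rose. TCF and LEF factors and their co-factors fell by 0.30 (exact permutation p = 0.0238, adjusted p = 0.0476), with the repressor Tcf7l1 lower (−1.52) and Tcf7 (0.83) and Lef1 (0.80), themselves WNT targets, higher among 12, of which 5 fell and 2 rose.

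Imprinted genes had a score difference of 0.27 (adjusted p = 0.0529): 7 of 16 rose, such as the growth factor Igf2 (0.98) and Mest (0.99), and Snrpn (−1.50) and Nnat (−1.41) fell. Collagens differed by 0.34 (adjusted p = 0.373; 0.14 without the library labelled mutant 4), with Col1a1 at 2.29 and past the threshold, and ribosomal proteins by 0.15 (adjusted p = 0.373). Placental prolactins differed by 2.78 (adjusted p = 0.0508), and by 1.65 without the library labelled mutant 4, and 3 of 12 rose. The library labelled mutant 4 held 23750 scaled counts of Prl4a1 and 9979 of Prl3d1, against at most 234 and 2703 in any WT embryo, and 4627 of the embryonic globin Hbb-bh1 and 1185 of Hba-x, against at most 240.4 and 3.41. Mutant 3 had the highest scaled count of the decidual prolactin Prl8a2 (7017). This gene is 1 of the 3 that rose and is also in the maternal list.

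Posterior Hox and allantois genes rose while epiblast and paraxial genes fell. A later stage alone would not give the fall of the paraxial list, whose genes are made throughout later stages (−3.191, SD of 0.353 in WT and 1.47 in mutants). The list was fixed beforehand, but its fall is part of the pattern and was already known, so it is not a separate test. The rise of posterior Hox genes and the fall of the NODAL list go with a later stage. An earlier stage is argued against by the score of the NODAL list, whose genes are highest early in gastrulation, at −2.102 (SD of 0.416 and 0.75). That fall was also known when the test was chosen, and it was not shared by each member. Of 10 members 5 fell and 2 rose, among them Mixl1 (2.32). Nodal (−1.70), Eomes (0.19) and Gsc (0.57) were not past the threshold. A difference in depth is argued against as well, since 96.9% of the calls (3755 of 3877) remained in the same direction after each library was thinned to the smallest. A larger share of extra-embryonic mesoderm cannot be told apart from a change of expression within cells. The 13 members of that list outside the Hox clusters had a median log2 fold change of 0.638, and 2 of them, Cdx4 and Tbx4, reached the lower quartile of the Hox genes of groups 5 to 13 (2.76). Hand1 (−0.09) and Foxf1 (0.39) did not, and neither was past the threshold. Whether their WT levels (10290 and 3011 scaled counts) hide an added share was not tested. A change of expression within cells was not tested, since whole-embryo RNA does not show where a gene is made, and the share of other cell types and the state of the alleles stay open.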
